A study of Mus musculus with 12 samples.

How the data were processed

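Gene expression was measured in the posterior neural tube of CD1 (outbred) mouse embryos at embryonic day 9.5. Per the labels' protocols, embryos were treated with pancreatin (2 mg per ml, 1 min), a digestive enzyme mixture that loosens tissue layers, and the tube was freed from neighbouring tissue with needles and divided into 6 pieces. The pieces are numbered 1 to 6, the labels do not state which number is the caudal end, and values are therefore given by part number. Per the series' design text, tissue came from 2 embryos, and each piece has 2 biological replicates, giving 12 Affymetrix arrays. RNA was labelled with biotin after a double amplification, per the labels' protocols, a procedure that shortens the copied RNA toward its 3′ end.

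The deposited values are linear array intensities, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. The version and settings of that program are not given in the sources used here. The trimmed mean of the deposited signal, with the highest and lowest 2% of probe sets left out, was 100 on every array, a global scaling that makes the arrays comparable when most genes do not change. The median signal per array lay between 16.7 and 19.1. Detection calls were not used here, so a low signal cannot be told from background, and signals of a few units carry no order. The number of arrays, 2 per piece, limits the precision.

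Of 45101 probe sets, 64 were controls and were left out of the tests. GEO's platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211; only the first kind was used. Of these, 34754 matched the reference gene table by Entrez identifier, and the others kept the symbol of the annotation. Coordinates were not used. A probe set was kept when its signal exceeded the median of its own array in at least 2 of the 12 arrays, which left 21679. Each gene was represented by its kept probe set with the highest mean, giving 12089 genes. Signals were transformed as log2(signal + 4.43), the offset being 0.25 of the median of all signals (17.7), with no further normalization. Log2 differences are on this scale and understate the change of genes with low signal.

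Models were fitted with limma 3.58.1 in R 4.3.3, with moderated statistics and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05; every adjusted p for a gene is from these limma fits unless another setting is named. The slope of the log2 signal per part number was fitted over all 12 arrays. A fit with 1 coefficient per piece gave the F test among the 6 pieces, part 6 against part 1, and the 5 comparisons of consecutive pieces, all sharing 1 estimate of the spread. A gene was counted as highest or lowest in an inner piece when it passed the F test, its extreme mean lay in parts 2 to 5, and both arrays there lay beyond every array of parts 1 and 6. Replicate 2 was compared with replicate 1 with the piece as a covariate. There were 29 gene lists, including markers of tissues that a dissected piece could hold. The 28 lists with at least 3 tested members were tested on the slope with limma's camera (two-sided, preset inter-gene correlation 0.01), adjusted over the lists.

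The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 largest slopes in each direction with the same sign in both embryos, and the 6 largest differences in each direction between parts 6 and 1 whose arrays did not overlap. It further named the 2 largest per direction between consecutive pieces, the 5 largest each for inner highest and inner lowest, the 3 largest per direction between replicates, sex-linked genes, and up to 4 members per list with the smallest trend p. Genes known only by a clone or predicted-gene symbol were passed over. Further genes are said to have been chosen after their values were seen.

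The replicate number was checked as a mark of the embryo. The deviations of same-numbered arrays from their piece means correlated across genes in all 15 pairs of pieces (0.175 to 0.325, median 0.226), and Xist and the Y-linked genes separated the numbers in all 6 pieces. With the design text naming 2 embryos, the numbers were taken to pair the arrays, and the fit with the embryo as a block is given where it changes a call. Each part's p-values rest on only 2 embryos. Same-numbered pieces come from 1 animal, so the fits without the block treat arrays of an embryo as independent.

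The analysis steps were tested on simulated data with 12089 genes. A slope of 0.25 log2 per part was recovered for 70% of 100 changed genes and one of 0.5 for 96%, with 12 false calls. The F test recovered 29% and 85% of the same genes with 3 false calls. For part 2 against part 1, a difference of 1 log2 was recovered for 39% of genes and one of 3 for 98%, with 5 false calls. The inner-piece rule recovered 94% of 50 genes raised by 3 log2 in part 2, with 3 of the 50 meeting the rule for lowest and 5 false calls, and the replicate comparison recovered 72% at 1 log2 and 98% at 2 log2, with 8 false calls. The simulated shifted list was recovered at 0.3 log2 per part, with 0 false lists. All simulated genes and arrays were drawn independently, so the false calls do not cover correlation between genes of a list or between arrays of an embryo.

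Alternatives covered quantile normalization, the offset, the filter, the variance prior, the choice of probe sets, array weights, the embryo block, each array left out in turn, the slope without either end piece, fits on only the 4 arrays of a pair of pieces, and, for lists, an estimated correlation and limma's fry. Added after seeing the data were the slope within each embryo, the ratio of 3′ to 5′ control probe sets as a covariate, 2 contrasts of non-consecutive pieces, and the difference of slopes between embryos.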

Results

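The data describe gene expression along the length of the embryonic day 9.5 mouse posterior neural tube, the tissue that forms the spinal cord and that is still being laid down at its caudal end at this stage. Each of 6 numbered pieces was measured on 2 arrays, 1 from each of 2 embryos, and 12089 genes were tested. Arrays of the same piece correlated across genes with r from 0.952 in part 1 to 0.980 in part 5, though genes are not independent replicates. Except in part 2 and in replicate 2 of part 5, every array correlated more strongly, on average, with neighbouring pieces of its own embryo. In part 1 these means were 0.969 and 0.963. The first principal component, with 38.4% of the variance, ordered the arrays by part number, from -49.3 and -40.8 in part 1 to 30.7 and 35.0 in part 6. The second, with 15.3%, put all arrays of replicate 1 below 0 and all arrays of replicate 2 above 0.

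The first question was how expression changed along the part number. Part 1 was rich in transcripts of the caudal growth zone and part 6 in transcripts of patterned neural progenitors. Cyp26a1, an enzyme that degrades retinoic acid, fell from a signal of 3058 ± 225 in part 1 to 22.7 ± 8.48 in part 6 (SD, n = 2), a slope of -1.49 ± 0.13 log2 per part (SE). The growth factor Fgf17 dropped from 529 ± 47.0 to 11.2 ± 6.44. Hes7, an oscillating gene of the segmentation clock, dropped from 1126 ± 413 to 16.1 ± 2.12, but among the gene lists it is a marker of presomitic mesoderm. In the opposite direction, Irx3, a homeobox gene of neural progenitors, rose from 40.6 ± 1.91 to 2711 ± 95.5, and the proneural gene Neurog2 from 1.43 ± 1.54 to 351 ± 3.69. The limma slope test, adjusted by Benjamini-Hochberg, called 1534 genes, of which 682 rose and 852 fell. Without both arrays of part 1 the test called 902 genes, and without both of part 6 it called 988.

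Among the genes with the largest positive slopes were the transcription factors Rfx4 (1.34 ± 0.12 log2 per part) and Irx5 (1.03 ± 0.065) and the Hox cofactors Meis2 (1.02 ± 0.11) and Meis1 (0.95 ± 0.051). Other steep slopes were 1.17 ± 0.056 for Ndnf, 1.16 ± 0.046 for Scube2, which releases Hedgehog protein from producing cells, 1.10 ± 0.072 for the endothelin receptor Ednrb, 1.03 ± 0.055 for Fgf14 and 0.94 ± 0.042 for the adhesion molecule Nrcam. Second, dimmer probe sets had smaller slopes in the same direction for Ednrb (0.18) and Ndnf (0.42), as had 2 further probe sets of Meis1 (0.68 and 0.31) and 3 of Nrcam (0.64, 0.64 and 0.15). Scube2 had the smallest adjusted p of the limma slope test, 8.52e-09. Pcdh8, a protocadherin, also rose, by 1.05 ± 0.23, but its 2 arrays in part 2 were far apart, at 607 and 6.83, and its call was lost without both arrays of part 1 (limma adjusted p = 0.121).

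Large negative slopes belonged to the endothelial and mesodermal receptors S1pr3 (-1.34 ± 0.28) and Aplnr (-1.26 ± 0.32), the extracellular protein Adamtsl2 (-1.17 ± 0.12), the scavenger receptor Scara5 (-1.16 ± 0.19) and Lypd6b (-1.15 ± 0.096). Gad1, which makes the transmitter GABA, fell by 1.12 per part, from a signal of 732 ± 364 to 13.8 ± 0.418. The haematopoietic factor Lmo2 had a slope of -1.07 ± 0.13. Second, dimmer probe sets had slopes of -0.78 for S1pr3 and -0.62 for Aplnr. The antisense RNAs Hoxa11os (-1.09 ± 0.17) and Evx1os (-1.03 ± 0.058) fell too. Aplnr and S1pr3 were uneven between embryos, Aplnr being at 2740 and 632 in part 1 and at 1490 and 24.2 in part 2, and the limma call for the slope of Aplnr was lost without either part 1 array (adjusted p = 0.0833 without replicate 1 and 0.0555 without replicate 2). Without both part 1 arrays the calls for Scara5 (0.0631) and Aplnr (0.293) were lost.

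**Figure D1:**
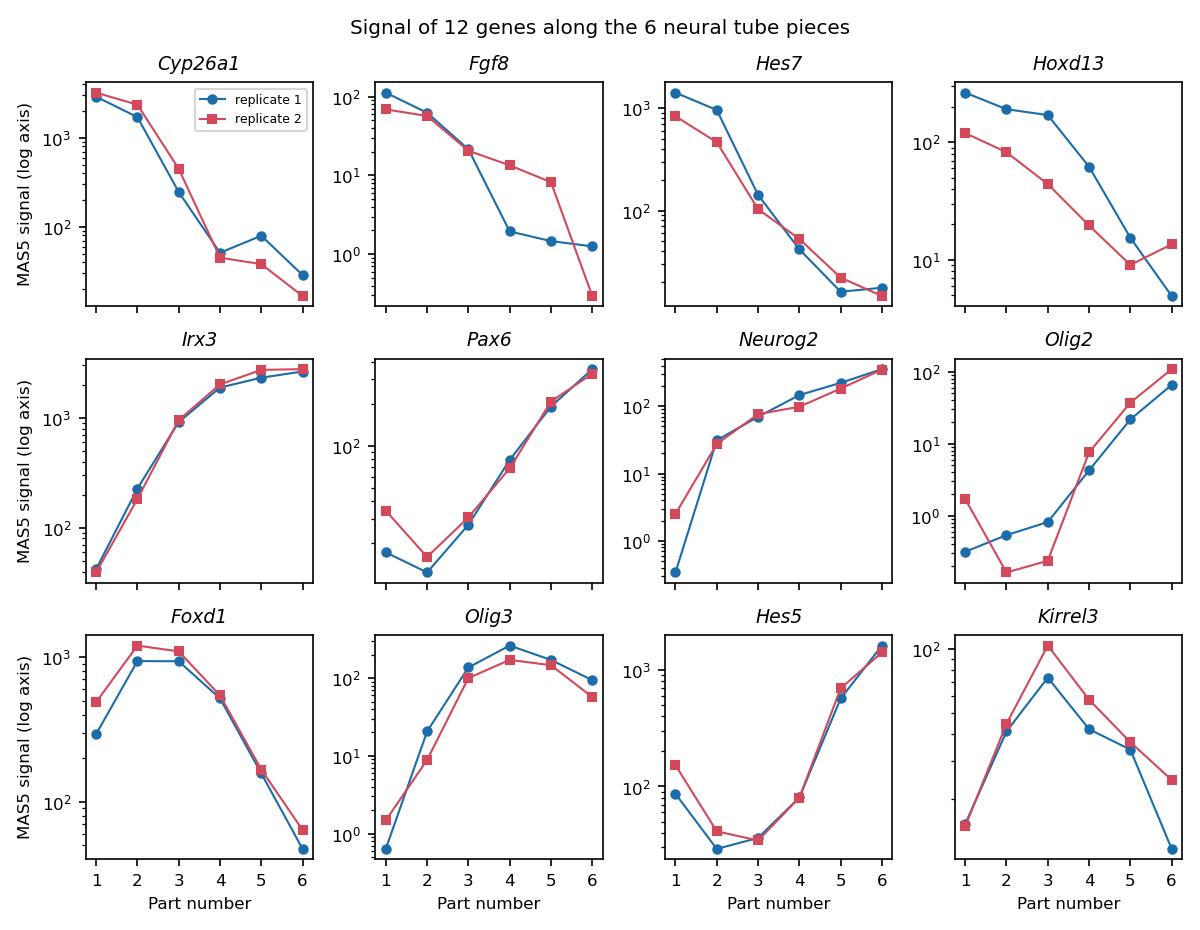
MAS5 signal (log axis) of 12 genes against part number, 1 point per array, with blue circles for replicate 1 and red squares for replicate 2; lines join the arrays of an embryo. Cyp26a1, Fgf8, Hes7 and Hoxd13 fell along the part number, Irx3, Pax6, Neurog2 and Olig2 rose, Foxd1, Olig3 and Kirrel3 were highest in an inner piece, and Hes5 was lowest in parts 2 and 3.

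The caudal progenitor list held 15 tested genes, of which 11 fell, 0 rose and 4 did not pass; adjusted over the list alone the count was also 11. Besides Cyp26a1 and Fgf17, it included Evx1 (-0.89 ± 0.052 log2 per part), a caudal homeobox gene, and Fgf8 (-0.88 ± 0.080). Genes of the FGF response fell in 5 of 10 cases and rose in 0, and adjusted over the list alone 5 fell. These included the feedback inhibitors Spry4 (-0.53 ± 0.055) and Dusp6 (-0.70 ± 0.089) and the ETS factor Etv4 (-0.46 ± 0.061, and -0.18 for a second, dimmer probe set). Of 12 Wnt targets and feedback genes, 4 fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose; Apcdd1 (-0.35 ± 0.035) and Sp5 (-0.38 ± 0.066) were among those that fell, and 5 other, dimmer probe sets of Apcdd1 had slopes of -0.38, -0.28, -0.17, -0.17 and -0.10. limma's camera gave adjusted p = 4.79e-11 for the caudal progenitor list, 3.06e-05 for the FGF response and 0.0505 for the Wnt list. The caudal progenitor list passed also when the correlation between genes was estimated (adjusted p = 0.00564 with an estimated correlation), and the FGF list did not (adjusted p = 0.127 with an estimated correlation). Only 3 other lists, neural progenitor, ventral and dorsal, held in that setting.

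Among markers of other tissues, the presomitic mesoderm and surface ectoderm lists passed on the same axis with the preset correlation. Both also passed, as lower, with limma's fry (adjusted p = 0.000659 and 0.000925), and neither passed with an estimated correlation. Of 8 presomitic mesoderm genes, 4 fell and 1, Pcdh8, rose, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.00582, lower; adjusted p = 0.272 with an estimated correlation). Rspo3, which enhances Wnt signalling, had a slope of -0.97 ± 0.092 (-0.57 for a second, dimmer probe set) and the Notch ligand Dll3 of -0.66 ± 0.096. Of 10 surface ectoderm genes, 7 fell and 0 rose, and adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 0.000434, lower; adjusted p = 0.147 with an estimated correlation). The keratins Krt8 (-0.66 ± 0.11) and Krt18 (-0.40 ± 0.060) and the epithelial adhesion genes Cdh1 (-0.70 ± 0.12) and Epcam (-0.55 ± 0.093, and -0.21 for a second, dimmer probe set) were among them. Krt8 had a signal of 299 ± 213 in part 1 and 33.6 ± 1.30 in part 6.

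Posterior Hox genes fell, and most anterior ones did not pass. All 6 tested genes of Hox paralogue groups 10 to 13 fell, over all genes and adjusted over the list alone (camera adjusted p = 2.07e-06; adjusted p = 0.0721 with an estimated correlation). Hoxd10 dropped from 818 ± 137 to 38.2 ± 29.3, and Hoxa11, Hoxd11 and Hoxd13 had slopes of -0.85 ± 0.13, -0.82 ± 0.088 and -0.84 ± 0.11. Of 9 genes of groups 6 to 9, 4 fell over all genes and 9 fell when adjusted over the list alone, with 0 rising (camera adjusted p = 8.53e-05; adjusted p = 0.0721 with an estimated correlation); slopes were small, such as -0.29 ± 0.059 for Hoxa7 and -0.14 ± 0.026 for Hoxd8, and that of Hoxa7 did not pass without both arrays of part 6 (limma adjusted p = 0.112). Of 13 genes of groups 1 to 5, 2 fell and 1 rose in both counts, that over all genes and that adjusted over the list alone (camera adjusted p = 0.949), with Hoxd1 at -0.32 ± 0.034.

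Neural progenitor genes rose with the part number. Of 14, 8 rose, 1 fell and 5 did not pass; adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 1.12e-06; adjusted p = 0.0103 with an estimated correlation). Pax6 went from 25.7 ± 12.03 to 342 ± 18.2 and Sox21 from 32.4 ± 8.59 to 370 ± 30.3; other, dimmer probe sets of Pax6 had slopes of 0.12 to 0.41 against 0.84. Of 10 ventral neural tube and Hedgehog genes, 7 rose and 0 fell, and adjusted over the list alone 8 rose (camera adjusted p = 9.61e-08; adjusted p = 0.0128 with an estimated correlation). Slopes were 0.75 ± 0.055 for the floor plate gene Spon1 (0.22 for a second, dimmer probe set), 0.85 ± 0.094 for Nkx6-1, 0.85 ± 0.12 for the motor neuron progenitor gene Olig2 and 0.48 ± 0.066 for Nkx2-9. Of 11 dorsal genes, 5 rose and 0 fell, and adjusted over the list alone 6 rose (camera adjusted p = 0.000201; adjusted p = 0.0128 with an estimated correlation). Among them were Zic1 (0.91 ± 0.12), the roof plate signal Wnt1 (0.57 ± 0.061) and Pax3 (0.44 ± 0.056, and 0.28 and 0.33 for 2 dimmer probe sets).

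Of 21 genes of neurogenesis and neurons, 6 rose and 3 fell in both counts, that over all genes and that adjusted over the list alone (camera adjusted p = 0.0232, higher; adjusted p = 0.0721 with an estimated correlation). Neurog1, a proneural gene like Neurog2, rose by 0.91 ± 0.11 per part. Mnx1, known both in motor neurons and in the notochord and tail bud, had a slope of -1.03 ± 0.11, and Stmn2, a neuronal microtubule gene, of -0.26 ± 0.037. This list did not pass without replicate 1 of part 6 (adjusted p = 0.0525) or replicate 2 of part 6 (adjusted p = 0.0576). Without both arrays of part 6, neither this list nor the neural crest list passed (adjusted p = 0.112 for each). With the filter at the 75th percentile the neurogenesis list turned lower (adjusted p = 0.907) and the neural crest list did not pass (0.0953). Of 10 neural crest genes, 4 rose and 0 fell, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.00582; adjusted p = 0.105 with an estimated correlation). Foxd3, a crest specifier, went from 2.16 ± 0.345 to 89.4 ± 9.02 and Cdh6 from 97.0 ± 21.3 to 484 ± 14.5, the latter not called without both arrays of part 1 (limma adjusted p = 0.0769).

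Retinoid and Notch genes went both ways. Of 9 retinoid pathway genes, 4 rose and 1 fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.207). The retinoic acid synthesising enzyme Aldh1a2 rose from 17.9 ± 3.26 to 600 ± 18.2, opposite to Cyp26a1, and the receptor Rarb from 7.23 ± 1.49 to 101 ± 2.68, while the receptor Rarg had a slope of -0.26 ± 0.040. Of 13 Notch pathway genes, 2 rose and 2 fell in both counts, that over all genes and that adjusted over the list alone (camera adjusted p = 0.812). The Notch effector Hes5 rose by 0.90 ± 0.21 per part (0.34 for a second, dimmer probe set) and Hey1 had a slope of -0.19 ± 0.042. Notch2 also passed, but a second, dim probe set of it had a slope of -0.13. Without both arrays of part 6, Hes5 (limma adjusted p = 0.212) and Rarb (0.0945) were not called, and without both of part 1, Hey1 was not (0.0786).

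Other lists showed few calls. Of 15 G1/S genes, 2 rose and 0 fell, and adjusted over the list alone 3 rose (camera adjusted p = 0.00177, higher; adjusted p = 0.293 with an estimated correlation); Cdt1, which licenses replication origins, had a slope of 0.13 ± 0.032. That list lost its call without replicate 1 of part 1 (adjusted p = 0.0502) or both arrays (0.106), as did Cdt1 without both (0.184). Of 15 G2/M genes, 1 fell over all genes and 0 changed when adjusted over the list alone (camera adjusted p = 0.878). Of 19 glycolysis genes, 3 rose and 0 fell, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.693), with the glucose transporter Slc2a1 at 0.23 ± 0.039. Of 22 oxidative phosphorylation genes and 11 cholesterol synthesis genes, 0 passed in either count (camera adjusted p = 0.0663 and 0.132). Of 7 immediate early genes, 2 fell, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.681), with Egr1 at -0.32 ± 0.056, not called without both arrays of part 1 (limma adjusted p = 0.0624). Of 6 early embryonic progenitor genes, 2 rose and 1 fell, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.949), with Mycn at 0.24 ± 0.041. The gene that fell, Pou5f1 (-0.26 ± 0.081, limma adjusted p = 0.0499), lost its call with the embryo as a block (0.0532) and on leaving out any of 8 arrays (up to 0.142).

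Among the remaining markers of other tissues, 1 of 6 somite genes rose (Aldh1a2, which the neural tube also expresses and the retinoid list also holds) and 1 fell (Tcf15, -0.28 ± 0.049), in both counts (camera adjusted p = 0.599). Of 3 notochord genes, 1 rose in both counts (camera adjusted p = 0.878), and of 3 brain and hindbrain genes, 1 fell in both counts (Phox2a, -0.32 ± 0.062, limma adjusted p = 0.0995 without both arrays of part 1; camera adjusted p = 0.409). No tested gene passed in either count among 8 blood (camera adjusted p = 0.878), 3 endothelium (0.949), 4 gut and visceral endoderm (0.331) and 2 lateral plate mesoderm genes, the last too few for a list test. The camera direction was upward where the median slope was below 0 for the early embryonic progenitor list (mean also below 0) and the notochord list, and downward where the median of G2/M and the mean of endothelium were above 0, all with an adjusted p of at least 0.878. In total 12 of 28 lists passed with the preset correlation and 4 with an estimated one.

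**Figure D2:**
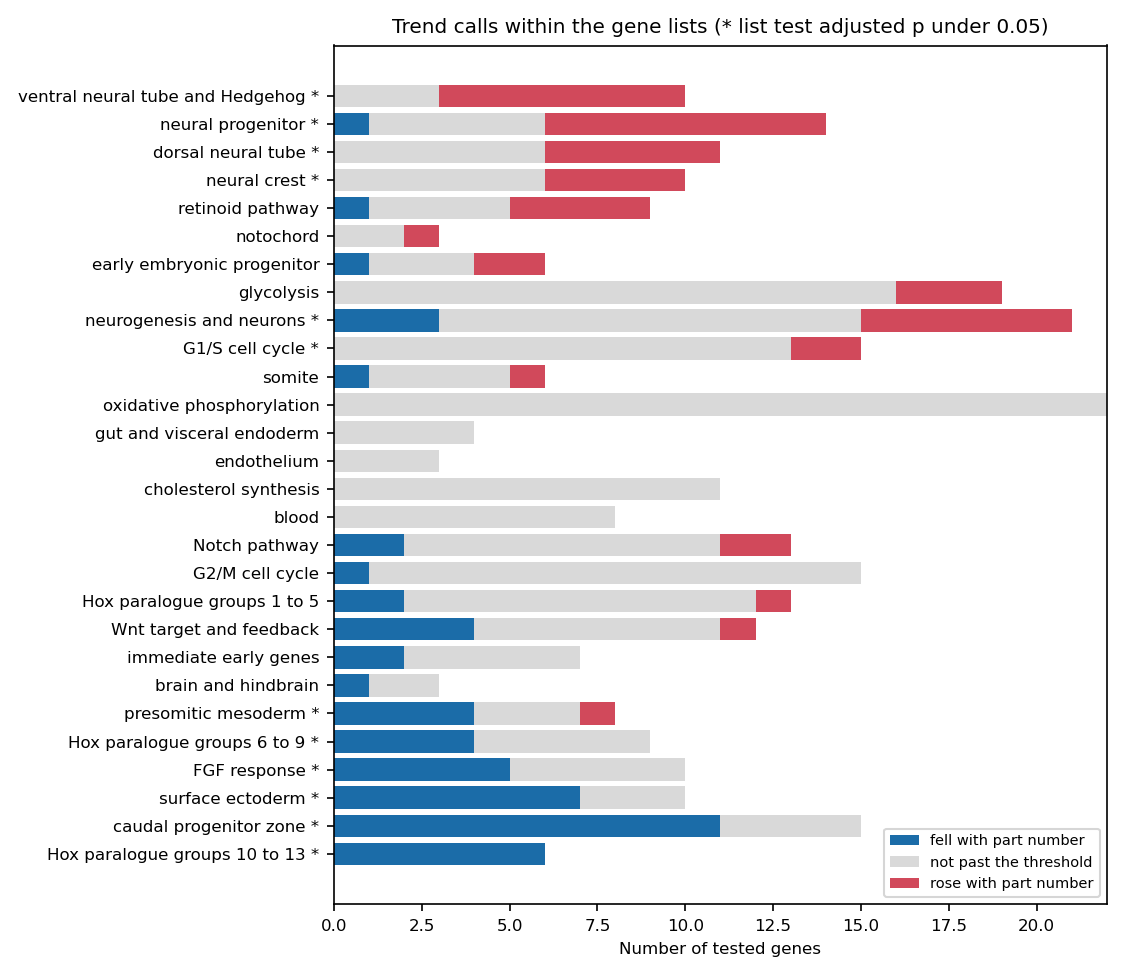
Number of tested genes (horizontal axis) that fell (blue), rose (red) or did not pass (grey) in the slope test over all genes, for the 28 lists with at least 3 tested members; an asterisk marks a camera adjusted p under 0.05. All 6 genes of Hox groups 10 to 13 and 11 of 15 caudal progenitor genes fell, and 7 of 10 ventral genes rose.

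Comparing the ends directly, the genes named as higher in part 6 were Rfx4 (6.40 ± 0.33 log2), Neurog2 (5.95 ± 0.24), Irx3 (5.91 ± 0.17), Pcdh8 (5.53 ± 1.49), Ndnf (5.49 ± 0.22) and Scube2 (5.46 ± 0.18). Those named as lower were S1pr3 (-7.36 ± 1.42), Aplnr (-6.94 ± 1.82), Cyp26a1 (-6.85 ± 0.38), Hes7 (-5.74 ± 0.36), Scara5 (-5.45 ± 0.35) and Lypd6b (-5.26 ± 0.29). The lower signals of Rfx4 and Neurog2 in part 1 and of S1pr3 in part 6 lay under the offset of 4.43, as did 1 of 2 arrays for Pcdh8 in part 1 (2.09) and for Aplnr in part 6 (3.20), so that the size and rank of these differences depend on the offset. The same holds for the slopes of Ednrb, Hoxa11os, Fgf8, Hoxd11, Mnx1, Cdh1, Nkx6-1, Olig2, Zic1 and Neurog1, whose signals at the lower end were under it. limma called 1088 genes, 500 higher and 588 lower in part 6, and 928 of them were also called by slope. Without replicate 1 or replicate 2 of part 6 the count was 607 or 480. The limma calls of the 3 genes with the largest errors depended on single arrays. The call was lost on leaving out any of 3 arrays for S1pr3 (replicate 1 of part 1 and both of part 6; adjusted p up to 0.0683), any of 8 for Aplnr (up to 0.175) and any of 9 for Pcdh8 (up to 0.185).

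Over all pieces, the limma F test called 591 genes as different somewhere among the 6 pieces, and 513 of these were also called by slope. The count was 375 without replicate 1 and 331 without replicate 2 of part 6. Among genes called by slope, a selection that itself favours gradual courses, the median gene that rose had covered 31.0% of its difference between the ends in part 2, 55.4% in part 3, 72.2% in part 4 and 90.9% in part 5, and the median gene that fell 23.9%, 53.1%, 67.4% and 83.9%.

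Steps between consecutive pieces were called for few genes, most of them early in the series. From part 1 to part 2, Neurog2 rose by 2.55 ± 0.24 log2 and Nr2f2, a nuclear receptor, by 2.54 ± 0.28, while Uap1l1 (-2.37 ± 0.24) and the receptor Gpr83 (-2.73 ± 0.31) fell; Gpr83 went from a signal of 164 ± 26.3 to 21.1 ± 5.31 and stayed near that level. From part 2 to part 3, Rfx4 (3.01 ± 0.33) and the dorsal progenitor gene Olig3 (2.74 ± 0.35) rose, and Scara5 (-3.27 ± 0.35) and Cyp26a1 (-2.58 ± 0.38) fell. Single genes passed at the later steps. Selplg rose by 1.68 ± 0.17 from part 3 to part 4, Hes5 by 2.90 ± 0.26 from part 4 to part 5 (80.3 ± 0.226 to 632 ± 89.5) and Plcd4 by 1.99 ± 0.18 from part 5 to part 6 (2.21 ± 1.24 to 21.9 ± 4.20). With no filter another probe set stood for Plcd4, and the step turned to -0.18. The lower signals of Neurog2, Selplg and Plcd4 at these steps lay under the offset of 4.43, as did 1 of 2 arrays for Nr2f2 in part 1 (3.02), which bounds the printed sizes.

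limma called 30 genes between parts 1 and 2 (20 higher, 10 lower), 58 with the embryo as a block, and the count was 111 without replicate 1 of part 1 and 11 without replicate 2 of part 2. It called 23 between parts 2 and 3 (11 higher, 12 lower), with 2 calls without replicate 1 of part 3, and 1 at each later step, with 390, 440 and 460 genes at an unadjusted p under 0.05. These 3 unadjusted counts lay below the 0.05 share of the 12089 tested genes that no difference would give. They therefore do not point to further changes under the threshold. Of the named steps only that of Neurog2 was called whichever single array was left out, and it lost its call with no offset, with array weights, where the comparison of parts 1 and 2 kept 1 call, and with only the 4 arrays of these pieces. Without replicate 1 of part 3 the adjusted p was 0.184 for Olig3, 0.103 for Scara5, 0.286 for Cyp26a1 and 0.165 for Selplg. It was 0.0599 for Nr2f2 without replicate 2 of part 1, 0.0565 for Gpr83 and 0.0906 for Rfx4 without replicate 1 of part 2, and 0.0560 for Uap1l1 without replicate 2 of part 2. Without replicate 2 of part 5 it was 0.282 for Hes5, and without replicate 1 of part 5 it was 0.0905 for Plcd4. The Cyp26a1 step also lost its call with the embryo as a block (limma adjusted p = 0.0630), and the Hes5 step when probe sets prone to cross-hybridization were left out (1.10 log2, limma adjusted p = 0.402).

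Some genes were highest or lowest in the middle of the series. Foxd1, a forkhead gene, was at 390 ± 137 in part 1, 1067 ± 185 in part 2, 1013 ± 112 in part 3 and 55.4 ± 11.7 in part 6. The growth factor Fgf18 was highest in part 2, by 1.62 log2 over the nearer end piece, Kirrel3, an adhesion molecule, in part 3 (2.09), and Olig3 (1.48) and Selplg (1.61) in part 4. The lowest values in an inner piece were those of Bmper, a modulator of BMP signals, in part 3 (-2.66), Fgf15 in part 3 (-2.10), Ets1, a crest and endothelial factor, in part 3 (-1.70) and Hes5 in part 2 (-1.61). The dorsal gene Pax7 was at 31.6 ± 15.8 in part 1 and 20.96 ± 3.35 in part 6, and at no more than 4.28 on any array of parts 2 to 5, too low to order those pieces. limma's F test with the placement rule gave 180 such genes, 96 highest and 89 lowest in an inner piece, some genes meeting both. These were 16.2% and 15.1% of the genes past the F test. Of simulated genes without any difference, 18.5% met the placement in 1 direction. The simulated genes were not selected by the F test, so these shares cannot decide whether the count of 180 exceeds chance. The rule sets no minimum margin and does not exclude genes with a called slope. Klf3 was highest in part 5 by only 0.071 log2 and Akr1b8 lowest there by -0.060, and both were also called by slope. Without replicate 1 of part 1 the count of genes highest in an inner piece was 156, and without replicate 2 of part 6 it was 68. Bmper and Fgf15 lost the call on leaving out any of 7 and any of 9 arrays (limma adjusted p up to 0.0900 and 0.136).

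The embryos differed in sex-linked genes and in others. Xist, the RNA that silences an X chromosome in females, had a signal of 651 to 1124 in the 6 arrays of replicate 1 and 19.5 to 29.7 in those of replicate 2. The Y-linked genes Eif2s3y, Kdm5d and Uty were higher in replicate 2, at 160 to 346, 81.4 to 100.4 and 42.9 to 89.6, against at most 7.29, 6.22 and 4.76 in replicate 1, too close to the offset of 4.43 to give the size of the difference. Xist was lower in replicate 2 (-4.85 ± 0.13 log2). Among other genes, Tmem14c (-2.96 ± 0.14) and Snx10 (-2.92 ± 0.20) were lower in replicate 2. limma called 196 genes, 87 higher and 109 lower in replicate 2, with a smallest adjusted p of 9.51e-07. The count ranged from 112 to 170 with single arrays left out, the lowest without replicate 2 of part 3. It was 113 with no filter, 322 with array weights, 495 with the filter at the 75th percentile and 610 with a variance prior that follows intensity. Other signals moved with the replicate number too. The signal of the 5′ control probe set of 18S RNA was 177 to 1109 in replicate 1 and 439 to 3170 in replicate 2, higher in replicate 2 in all 6 pieces. The Gapdh 3′ to 5′ ratio was lower in replicate 2 in 5 of 6 pieces, and the embryonic globin genes Hbb-y and Hbb-bh1, chosen after their values were seen, were higher there in 5 of 6.

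In replicate 1, some somite genes and Shh had high signals in part 2, and less so in part 1, that were lower on the matching arrays. Not all genes of other tissues followed this course. Aplnr was higher in part 1 (2740) than in part 2 (1490) of replicate 1. Cdh1 in part 2 was at 16.1 in replicate 1 against 57.6 in replicate 2. The somite genes Foxc2, Foxc1 and Meox1, chosen after their values were seen, had signals of 36.6, 49.1 and 26.6 in part 1 of replicate 1. In part 1 of replicate 2 they were at 1.05, 18.5 and 2.39, and Shh was at 71.0 and 26.2. On the array of part 2 of replicate 1 these somite genes were at 185, 168 and 109, against 1.15, 2.54 and 2.82 in replicate 2, and Shh was at 504 against 25.3. Without that array, limma called 1362 genes by slope, 1034 between the ends, 525 among the pieces, 13 between parts 1 and 2 and 6 between parts 2 and 3. The 3′ to 5′ signal ratio of the Gapdh control probe sets, which rises as RNA is shortened, was 9.39 and 8.50 in part 1 and 4.97 and 3.40 in part 6. Its log2 had Pearson r = -0.493 with the part number (permutation p = 0.104, adjusted over 2 control genes 0.208) and Spearman rho = -0.509 (permutation p = 0.0958, adjusted 0.192), two-sided over 12 arrays. Without part 1, r was -0.145, and within replicates 1 and 2 it was -0.800 and -0.400. For beta actin r was -0.189 (permutation p = 0.551) and rho was -0.297 (permutation p = 0.353).

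**Figure D3:**
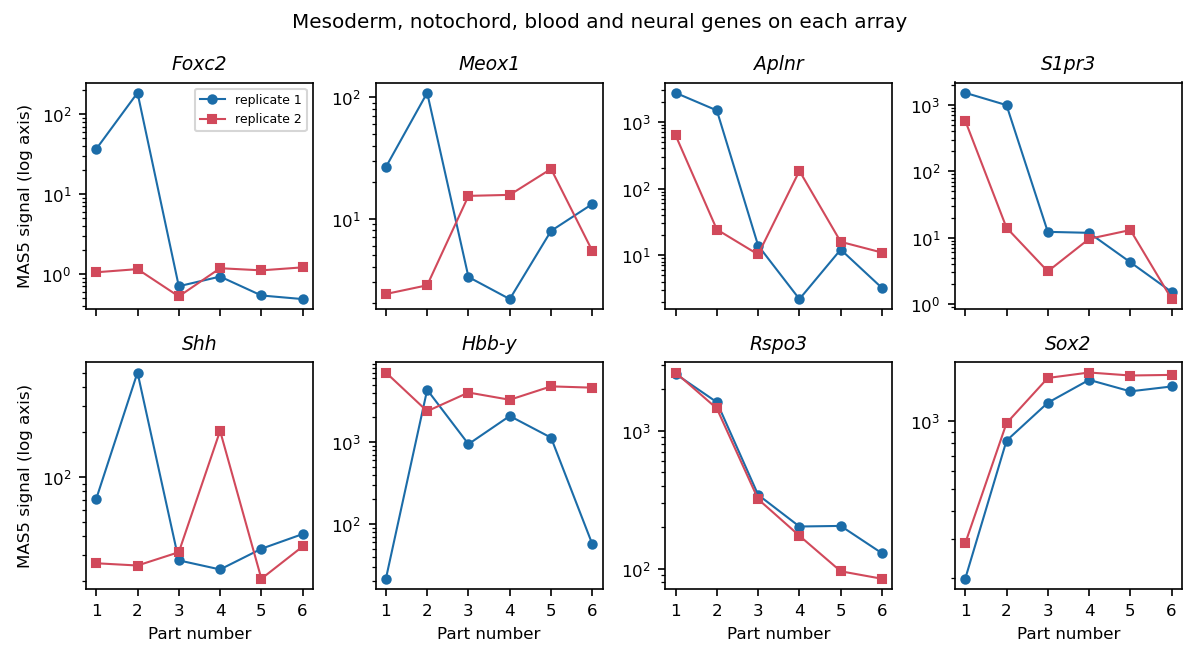
MAS5 signal (log axis) of 8 genes against part number, 1 point per array, with blue circles for replicate 1 and red squares for replicate 2; lines join the arrays of an embryo. Foxc2, Meox1, Aplnr, S1pr3 and Shh were far higher in part 2 of replicate 1 than of replicate 2, Hbb-y varied from 21.4 to 7060 and was higher in replicate 2 in 5 of 6 pieces, and Rspo3 and Sox2 changed alike in both embryos.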

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

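Of 127 values of named genes past the threshold, 69 stayed past it in the same direction under every alternative that could be run, 1 reversed, and 337 values under alternatives lost the call; the slopes within each embryo and with the 3′ to 5′ ratio were added after seeing the data. Quantile normalization left every count within 1.5 times (1544 genes by slope), and the median slope of all genes stayed between -0.0111 and -0.000267. With the replicate number as a block, 1817 genes were called by slope (1527 shared), 1473 between the ends (1087 shared) and 799 among the pieces (586 shared). The count rose to 58 for parts 1 and 2 and to 26 for parts 2 and 3, and stayed at 1 for each later step. The calls for the Cyp26a1 step and the Pou5f1 slope were lost, and no other named gene or list lost its call. The slope test called 902 genes (389 higher, 513 lower) without part 1 and 988 (529 lower) without part 6, both over a shorter range of part numbers, 450 (209 higher, 241 lower) without replicate 1 and 653 (252 higher, 401 lower) without replicate 2. With only the 4 arrays of the pieces compared, part 6 against part 1 gave 473 calls (224 higher, 249 lower) and each of the 5 consecutive comparisons 0 in limma. For these and the other settings the cause was not tested. Array weights gave 480 calls between the ends (247 higher, 233 lower), 1 for parts 1 and 2, 9 for parts 4 and 5, 8 for parts 5 and 6, and 322 between replicates. With no offset, parts 2 and 3 gave 11, parts 4 and 5 gave 2, and parts 5 and 6 gave 6; with an offset of 0.5 of the median, parts 3 and 4 gave 0, parts 4 and 5 gave 2, and parts 5 and 6 gave 3. With no filter, the steps into parts 2, 3, 4 and 6 gave 12, 8, 0 and 0 calls and the replicates 113, and Plcd4 reversed to -0.18 log2 from part 5 to part 6, another probe set then standing for the gene. With the filter at the 75th percentile, 56 genes were lowest in an inner piece, the steps into parts 2, 4, 5 and 6 gave 73, 3, 6 and 2 calls, the replicates 495, and the neurogenesis list turned lower (adjusted p = 0.907), fewer of its genes being tested; over its other alternatives with camera it was higher, with adjusted p from 0.00581 to 0.112. With a variance prior following intensity, the steps into parts 2, 4 and 6 gave 71, 3 and 0 calls and the replicates 610. Parts 4 and 5 gave 2 calls with the mean of a gene's probe sets and 0 without probe sets prone to cross-hybridization. Lists past the threshold numbered 4 of 28 with an estimated correlation. With limma's fry, every list that passed with the preset correlation passed. So did the Wnt (fry adjusted p = 0.0068), retinoid (0.000456), brain and hindbrain (0.0132) and gut and visceral endoderm (0.0462) lists. Leaving out each array in turn gave 1175 to 1536 genes by slope (523 to 678 higher, 619 to 898 lower), 12 to 13 lists, 331 to 558 genes among the pieces, 129 to 233 extreme in an inner piece (68 to 156 highest, 62 to 107 lowest), 480 to 1308 between the ends (239 to 757 higher, 241 to 726 lower), 11 to 111, 2 to 25, 0 to 1, 0 to 1 and 0 to 3 for the consecutive steps in order, and 112 to 170 between replicates; a piece then left with 1 array was assumed to vary like the others. Without detection calls, signals of a few units limit what can be said of low genes.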

Other observations

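The genes of the first 2 paragraphs, the 2 contrasts of non-consecutive pieces, the slope difference between embryos, the tests on part 2 of replicate 1 and the orientation hypothesis were chosen after results had been seen. Progenitor genes did not all follow a straight course. Sox2, a factor of neural progenitors, had signals of 199 and 286 in part 1, 820 and 981 in part 2 and 1210 and 1560 in part 3, and then stayed between 1360 and 1650. Nkx1-2, a gene of the caudal lateral epiblast and young neural tube, was at 1270 and 1890 in part 1, at 3190 and 2780 in part 3 and at 1020 and 938 in part 6. Fabp7, a lipid-binding protein of neural progenitors, was at 585 and 451 in part 1, 186 and 23.4 in part 2, and between 17.9 and 58.9 in parts 3 to 6. limma called 323 genes between parts 1 and 3 (182 higher, 141 lower in part 3) and 212 between parts 3 and 6 (109 higher, 103 lower in part 6). No gene's slope differed between the embryos after Benjamini-Hochberg adjustment in limma (0 calls, smallest adjusted p = 0.633, 799 genes at an unadjusted p under 0.05).

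Blood transcripts varied from array to array, and 0 of 8 blood genes passed the slope test. The embryonic globin gene Hbb-y had a signal of 21.4 in part 1 of replicate 1 and 7060 in part 1 of replicate 2, 4340 in part 2 of replicate 1, and 56.5 and 4610 in part 6. Hbb-bh1 was at 12.6 and 2700 in part 1 and at 13.6 and 1560 in part 6. Shh, a signal made by notochord and floor plate, was at 204 in part 4 of replicate 2 against 23.8 in replicate 1, and Aplnr was at 184 against 2.18. The epithelial genes Cdh1 and Esrp1 were at 106 and 103 in part 1 of replicate 1, at 26.8 and 14.3 in part 1 of replicate 2 and at 57.6 and 51.0 in part 2 of replicate 2.

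The course of expression along the part number was set against chance and RNA quality. Of 100 assignments of the part numbers to the arrays within each embryo, only the real one reached 1534 genes by slope (1 of 100, highest other 3). For differences among the pieces, too, only the real one reached 591 (1 of 100, highest other 364). Both results argue against chance. The assignment with 364 calls paired arrays that were 0.333 part numbers apart on average, against a median of 2. With the 3′ to 5′ ratio as a covariate, 76.1% of the called slopes stayed past the threshold with the same direction, and the median slope was 97.4% of its former size, which argues against shortened RNA as the whole cause. That part 1 is the caudal end stays a hypothesis, prompted by the lower caudal progenitor list (camera adjusted p = 4.79e-11) and Hox genes of groups 10 to 13, and no test independent of these lists was run. Position along the tube and the tissue attached to each piece may both contribute. On the same axis 7 of 10 surface ectoderm and 4 of 8 presomitic genes fell, and 1 presomitic gene rose. Neither list passed with an estimated correlation (camera adjusted p = 0.147 and 0.272), and both passed with limma's fry (adjusted p = 0.000925 and 0.000659).

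Genes differing between the embryos were set against chance and against faults of single probe sets. Of 32 splits with 1 array of every piece per group, only the real one gave 196 calls (1 of 32, highest other 0). The replicate number thus grouped the arrays more strongly than any other split, at the smallest share that 32 splits can give. With 1 embryo per group, the splits cannot tell the embryos from anything else that same-numbered arrays share. For the probe sets, Xist and the Y-linked genes were left out, but other X-linked genes, such as Eif2s3x and Kdm5c, were not. For 90 called genes with further kept probe sets, these carried a median of 40.7% of the difference (95% interval 27.0 to 46.6), against 68.3% (64.7 to 71.5) of the slope for 692 genes called by slope. Sequence variants of an outbred stock, or other faults of single probe sets, would give such a lower share, but it does not single them out. The called probe set was the brightest of its gene, and the offset compresses differences of dimmer ones. The 2 sets of genes were also not matched on signal or size of difference. For the X-linked genes the share was 74.5% for Eif2s3x and 31.5% for Kdm5c. Sex and genetic background of the embryos, blood content and RNA quality, which also moved with the replicate number, stay open, as only 1 embryo of each sex was measured.

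Mesodermal transcripts in part 2 of replicate 1 may come from mesoderm carried over in the dissection, which stays open. The 14 tested presomitic and somite genes had a median excess of 1.78 log2 in that array over replicate 2, relative to the same difference in the other pieces, which lay above 100% of 10000 random lists matched on mean signal; this describes the array that prompted the hypothesis and does not test it. The excess was 2.96 for somite, 1.45 for presomitic mesoderm, 1.80 for notochord and 2.41 for blood genes. It was -0.00468 for neural progenitor, -1.28 for surface ectoderm and -0.395 for caudal progenitor genes, and -0.322 for Hox groups 10 to 13. Among the 6 tested somite genes, Aldh1a2 is also made by the neural tube. Of the 6 somite genes, 5 were higher there than in every array of parts 1 and 3. This count was also taken after the excess had been seen, in 1 array. It therefore cannot decide whether that piece was cut more caudally. The caudal progenitor and posterior Hox lists had no excess there, but with 1 array the question stays open. No biological explanation was tested for this single array.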
